A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

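Transcript levels were measured on 6 Affymetrix yeast arrays, 3 hybridized with RNA of the wild-type Saccharomyces cerevisiae strain FY4 and 3 with RNA of a strain lacking GCR2. FY4 is a prototrophic laboratory strain of the S288C lineage. Per the labels, both strains grew in batch at 30 °C in minimal medium with glucose, and cells were taken in exponential growth. Total RNA was reverse-transcribed and transcribed in vitro with biotin-labelled nucleotides, per the labels. The labels give FY4 as the strain of the wild-type samples and give no strain for the deletion samples. They do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

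The authors deposited 1 table of summarised values for 10928 probe sets. Its values are probe-set intensities on a linear scale, between 9.14 and 37181, as deposited by the authors. Per the submitters' processing notes, R 2.8.0 with the affy package and RMA made these values; RMA corrects background, equalises the intensity distributions of the arrays and summarises the probes of each set. Equalising the distributions removes any change in the total amount of messenger RNA per cell or per amount of total RNA, so every change below is relative to the rest of the array. The genome build behind the probe annotation is not given in the sources used here. No column of the table was left unmapped, and no pair of arrays held identical values.

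The log2 of each intensity was taken here, with no pseudocount and no further normalization. The platform annotation gave 7244 probe sets exactly 1 gene, 1 probe set several genes, and did not list 3683. Gene identifiers were matched to the RefSeq annotation of assembly R64, used for names and neighbouring genes only; 5498 probe sets matched a S. cerevisiae gene and 12 tested symbols were updated. A further 1746 probe sets with 1 gene matched no gene in that annotation and belong to the other yeast species on the array. For the 47 genes with several probe sets the brightest was used, which left 5449 genes. Of the probe sets used, 116 are of types that can bind transcripts of several related genes. Background was set at the 95th percentile of the other species' probe sets, per array for single values and at an intensity of 76.7 for means. No gene was removed for low signal; 127 tested genes had a mean at or under that background. A gene under background on every array of a group has only a bound there, given as at least N-fold, with the background of each array in place of lower values.

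The deletion arrays were compared with the wild-type arrays by limma 3.58.1 (lmFit and eBayes, no covariates) in R 4.3.3. Tests were two-sided, with Benjamini-Hochberg adjustment over the 5449 genes, and a gene was called at an adjusted p under 0.05. A second count asked for a change of at least 2-fold as well. "Rose" and "fell" are used of called genes. Changes are log2 differences, deletion minus wild-type, with limma's standard error (SE); levels are mean ± SD of log2 intensity, n = 3 arrays. The number of arrays limits the precision: the median half-width of a gene's 95% interval was 0.15.

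Before the data were examined, 31 gene lists were fixed: glycolysis, other routes of carbon metabolism, transport, regulators, ribosome, biosynthesis, nutrient regulons, stress, proteasome, S phase, and markers of mating type, sporulation and auxotrophic strains. Lists with at least 5 measured members, 30 in all, were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. The genes named were also chosen by a rule fixed beforehand. It takes GCR2 with 5 annotated genes on each side, of which up to 3 are named; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap; all measured glycolytic genes; up to 4 members with the smallest adjusted p of each other list; and the mating-type and auxotrophic marker genes. Genes outside the rule are said to be chosen after their values were seen.

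Alternatives fixed beforehand were the replicate number as a block, leaving out each array in turn, quantile normalization or median centring over tested genes, median centring over genes in no list, removal of dim probe sets, averaging or separate testing of probe sets, array weights, an intensity-trended robust prior, an unmoderated statistic, an adjusted p under 0.01, limma's treat against 1.5-fold, and both other set tests. Alternatives chosen after seeing the data were leaving out together wild-type replicate 3 and deletion replicate 1, the array of each group farthest out along the first principal component, and centring each array on its poly-A spike-in controls.

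The test was run on simulated data with the 5449 genes' means and with spreads drawn from the distribution that limma fitted. In these data 50 genes each were changed by 0.3, 0.5, 1 and 2 on the log2 scale. Noise was independent between genes and followed limma's own model, so the rates below need not hold for the real data. It recovered 52%, 80%, 92% and 98% of them in that order, and 3.59% of all calls were false. A target of over 95% recovery at changes of 1 and 2, set before the simulation, was missed at 1. The mean estimate there was 0.99, and the genes missed were among the noisiest simulated, so the target was replaced by checks of the estimated sizes and of the false calls, and the recovery is given as found. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, control probe sets and plots.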

Results

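Expression was compared between 3 wild-type FY4 and 3 gcr2 deletion samples of Saccharomyces cerevisiae grown on glucose. The question was which transcripts depend on GCR2, which codes for an activator of glycolytic gene transcription. Between 96.8% and 97.9% of the 5449 tested genes lay above background on each array. The first principal component held 61.8% of the variance and separated the groups, with wild-type replicate 3 and deletion replicate 1 farthest out along it.

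GCR2 itself was at 11.11 ± 0.05 in wild-type and at 4.59 ± 0.15 in the deletion, under background on all 3 deletion arrays. It was at least 27.5-fold lower in the deletion (limma adjusted p = 1.01e-06), as the labels state. Of the 5 annotated genes on each side in assembly R64, 1 (NNR1) was not measured. YNL194C rose by 0.30 (adjusted p = 0.0094), a call lost in 1 of 16 alternatives. Its level was close to background, at 6.46 ± 0.05 in wild-type and 6.77 ± 0.05 in the deletion, and above background on 2 of 3 wild-type arrays. YNL193W rose by 0.13, a call lost in 13 of 16. WHI3, the adjacent gene on one side, differed by 0.17 with groups that did not overlap (adjusted p = 0.14), and the nearest measured gene on the other side by -0.04; neither was called.

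Of the tested genes, 1224 were called, 769 higher and 455 lower in the deletion, among them 10 that were under background on all 6 arrays. Most changes were small: 51 genes changed at least 2-fold, 24 up and 27 down, and the median change of all genes was 0.02. For 2465 genes (45.2%) the groups did not overlap, against 10% by chance. The number called was 786, 1225 and 1011 without wild-type replicates 1, 2 and 3. It was 483, 543 and 406 without deletion replicates 1, 2 and 3, and 328 without both wild-type replicate 3 and deletion replicate 1.

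Control probe sets outside the gene tests also differed between groups. Those for 18S ribosomal RNA were at 14.10 ± 0.08 in wild-type and 12.95 ± 0.15 in the deletion, and those for 25S at 13.44 ± 0.13 and 11.94 ± 0.48. Poly-A spike-in controls, bacterial transcripts added to the RNA before labelling, were at 8.52 ± 0.39 and 7.67 ± 0.24. Hybridization controls, added after labelling, were at 11.51 ± 0.03 and 11.35 ± 0.23. Centring each array on the poly-A controls raised the median change of all genes by 0.86, to 0.88, and gave 4891 called genes, 4882 of them higher. All changes are therefore given relative to the bulk of each array's signal. That does not remove a difference in RNA preparation between the groups. The labels name no preparation batch, so such a difference cannot be told apart from the deletion.

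**Figure D1:**
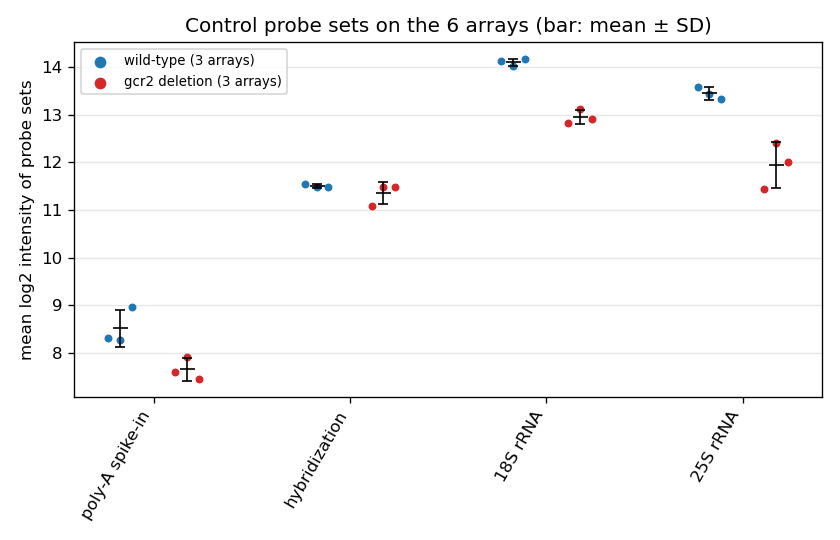
Mean log2 intensity of 4 kinds of control probe sets (vertical axis) on each of the 6 arrays, blue for wild-type and red for the gcr2 deletion, with mean ± SD in black. Ribosomal RNA and poly-A controls lie lower on all 3 deletion arrays, whereas the hybridization controls of 2 of the 3 deletion arrays lie close to wild-type.

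Glycolytic genes responded unevenly. Of 16 measured members, 5 fell, 2 rose and 9 did not pass the test (6 fell and 2 rose when adjusted over the list alone). The falls were in the lower part of the pathway and at 1 upper step. ENO1 and ENO2, the enolases, fell by 0.74 (SE 0.05, adjusted p = 0.00088) and 0.33 (SE 0.04, adjusted p = 0.0049). GPM1, phosphoglycerate mutase, fell from 14.93 ± 0.02 to 14.25 ± 0.05, which is 1.60-fold lower (adjusted p = 0.00058). PGI1, phosphoglucose isomerase, fell by 0.44 (adjusted p = 0.0034), and CDC19, the main pyruvate kinase, fell by 0.28 (adjusted p = 0.0079). CDC19 lost its call without both wild-type replicate 3 and deletion replicate 1.

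GLK1, glucokinase, rose by 0.88 (SE 0.10, adjusted p = 0.0035), from 13.24 ± 0.18 to 14.12 ± 0.04. HXK2, the main hexokinase on glucose, rose by 0.18, a call lost in 11 of 16 alternatives. Members that were not called differed by -0.26 (HXK1), -0.16 (PFK1), -0.11 (TDH1), -0.10 (TPI1), -0.08 (FBA1), -0.05 (TDH3), -0.04 (PGK1), -0.01 (PFK2) and 0.27 (PYK2). Most of them were at 14 or above on the log2 scale, among the brightest probe sets of the array, where 6.04% of 149 genes outside the list were called, against 22.0% at log2 10 to 13. The list's median was -0.10, lower in 13 members and higher in 3. Camera placed it below other genes (adjusted p = 0.0056); with an estimated correlation the adjusted p = 0.72. In all, camera called 8 of the 30 lists; with an estimated correlation it called 0 (2 at an unadjusted p under 0.05), and fry called 16. Another split of the same 6 arrays, mixing the groups, gave 10 called lists with the preset correlation.

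**Figure D2:**
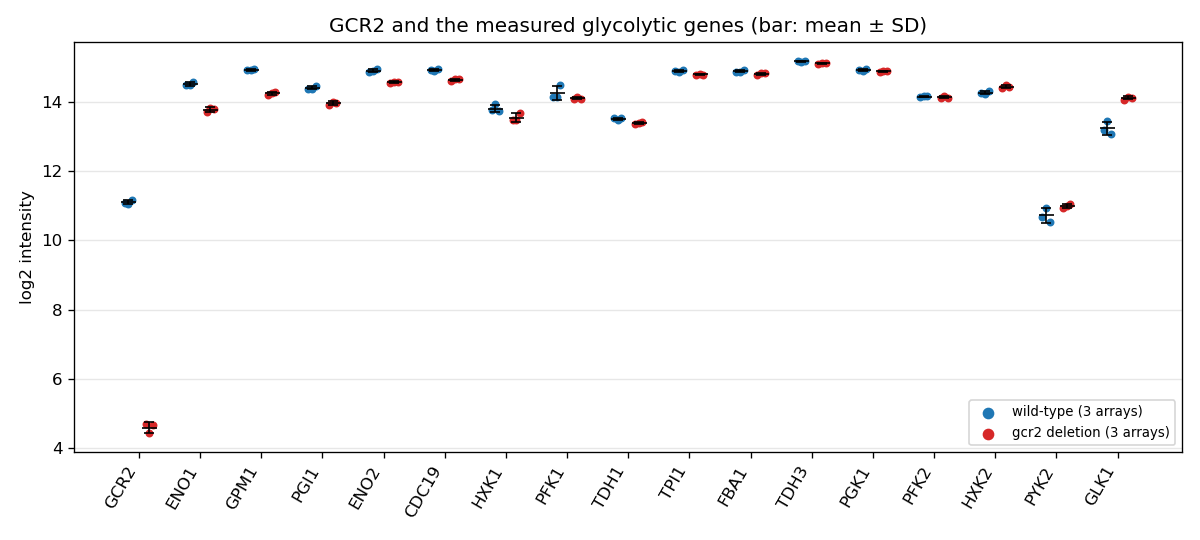
Log2 intensity (vertical axis) of GCR2 and the 16 measured glycolytic genes on each array, blue for wild-type and red for the deletion, with mean ± SD in black. GCR2 drops to background, ENO1, GPM1, PGI1, ENO2 and CDC19 are lower, and GLK1 is higher on all 3 deletion arrays.

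Several regulators of carbon metabolism fell. Of 25 members, 9 fell, 2 rose and 14 did not pass (9 and 7 adjusted over the list alone). GCR1, whose product acts with Gcr2, fell by 0.95 (SE 0.08, adjusted p = 0.0014). CAT8 and ADR1, activators of genes for growth without glucose, fell by 1.35 (SE 0.13, adjusted p = 0.0025) and 1.04 (SE 0.07, adjusted p = 0.00078). MIG1, a repressor acting on glucose, fell by 0.58. Camera did not call the list (adjusted p = 0.22), whereas fry did (adjusted p = 0.026). Among 17 members of the hexose transport list, 4 fell, 1 rose and 12 did not pass. Again fry called the list (adjusted p = 0.015) and camera did not (adjusted p = 0.16). HXT2 fell by 1.30 (adjusted p = 0.00032), and HXT7, on a probe set that can bind related transcripts, fell by 1.12. HXT1, a low-affinity transporter, rose by 0.85 (adjusted p = 0.011). HXT8, counted among the 4, was under background on all 6 arrays, and its call was lost in 10 of 15 alternatives.

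Genes of branches leaving glycolysis were among those that rose. In glycerol metabolism 6 of 11 genes rose, 2 fell and 3 did not pass, with a median of 0.49. GPP2, glycerol phosphatase, rose 2.61-fold (change 1.38, SE 0.04, adjusted p = 4.71e-05), GPD1, glycerol-3-phosphate dehydrogenase, by 0.60, GCY1 by 0.53 and DAK1 by 0.49. The list's adjusted p was 0.098 with camera and 0.0014 with fry. In the pentose phosphate pathway 7 of 16 rose, 1 fell and 8 did not pass (11 and 1 adjusted over the list alone). GND1 rose by 0.34 and ZWF1, the entry enzyme, by 0.34, and RKI1 fell by 0.27. Camera called that list (adjusted p = 0.026), but not with an estimated correlation (adjusted p = 0.67) nor without wild-type replicate 2 (adjusted p = 0.061). Among 7 ethanol fermentation genes ADH5 rose by 1.52 (adjusted p = 0.00049) and ADH4 by 0.61, and 5 did not pass, with a list median of 0.02 that turned to -0.01 when arrays were centred on genes in no list.

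Acetate and acetyl-CoA genes went both ways, with 2 of 12 up, 3 down and 7 not called. ALD6 fell by 0.56 and ALD5 by 0.41, and ACH1 rose by 0.45. The list's median was 0.03, its mean -0.03 and camera's direction down. In the tricarboxylic acid cycle 6 of 19 rose, 2 fell and 11 did not pass; CIT1 rose by 0.25 and FUM1, with the list's smallest adjusted p, by 0.21. In the glyoxylate cycle and gluconeogenesis MDH2 rose by 0.84 and the other 10 genes did not pass. For the respiratory chain and ATP synthase 2 of 37 rose, 1 fell and 34 did not pass, with NDE1 down by 0.50. Trehalose and glycogen genes rose in 6 of 17 and did not pass in 11, with NTH1 up by 0.44 and TPS2 by 0.58. Camera called the list only in 2 settings. They were without wild-type replicate 2 (adjusted p = 0.049), and with every probe set of the array tested on its own, other species and controls included. Of 13 genes for galactose, maltose and sucrose use 5 rose, 1 fell and 7 did not pass, with GAL7 up by 0.63 and MAL33 down by 0.79. Camera called that list without deletion replicate 2 (adjusted p = 0.032) but not with all arrays (0.075), and fry called it with all arrays (0.029).

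YGP1 and YRO2, stress-induced genes for a cell wall glycoprotein and a membrane protein, showed the largest rises of the tested genes. YGP1 went from 10.34 ± 0.14 to 14.18 ± 0.02, 14.3-fold higher (adjusted p = 4.15e-06). YRO2 went from 8.95 ± 0.07 to 12.43 ± 0.06, 11.1-fold higher (adjusted p = 1.93e-06). Of 33 stress genes 14 rose, 1 fell and 18 did not pass (16 and 1 adjusted over the list alone). HSP26, a small heat shock protein gene, fell by 1.37 (SE 0.07, adjusted p = 0.00025), against the list's direction. The list's median was 0.32 (camera adjusted p = 0.00046; adjusted p = 0.72 with an estimated correlation). Of 23 oxidative stress genes 4 rose, among them OYE2 by 0.46, 2 fell, among them GPX2 by 0.58, and 17 did not pass.

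Ribosome biogenesis genes fell in 11 of 53 and did not pass in 42. Changes were small, with a list median of -0.14. NOP53 fell by 0.46, NOP13 by 0.26, BRX1 by 0.20 and NOP16 by 0.20. Each of these calls was lost in at least 5 of 16 alternatives. Camera called the list (adjusted p = 1.09e-05), but not with an estimated correlation (adjusted p = 0.72), and fry did not call it (adjusted p = 0.085). Among 127 cytosolic ribosomal protein genes only RPS9A was called, down by 0.22, and the list's median was -0.0004. Camera did not call that list (adjusted p = 0.22) except without wild-type replicate 3 (adjusted p = 0.0072) or without both it and deletion replicate 1 (0.014). On the same deletion arrays the 18S and 25S ribosomal RNA controls were 2.23-fold and 2.83-fold lower. The poly-A controls, which were added to the RNA, were 1.81-fold lower as well. The ribosomal RNA controls are therefore not read here as the ribosomal RNA content of the cells.

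**Figure D3:**
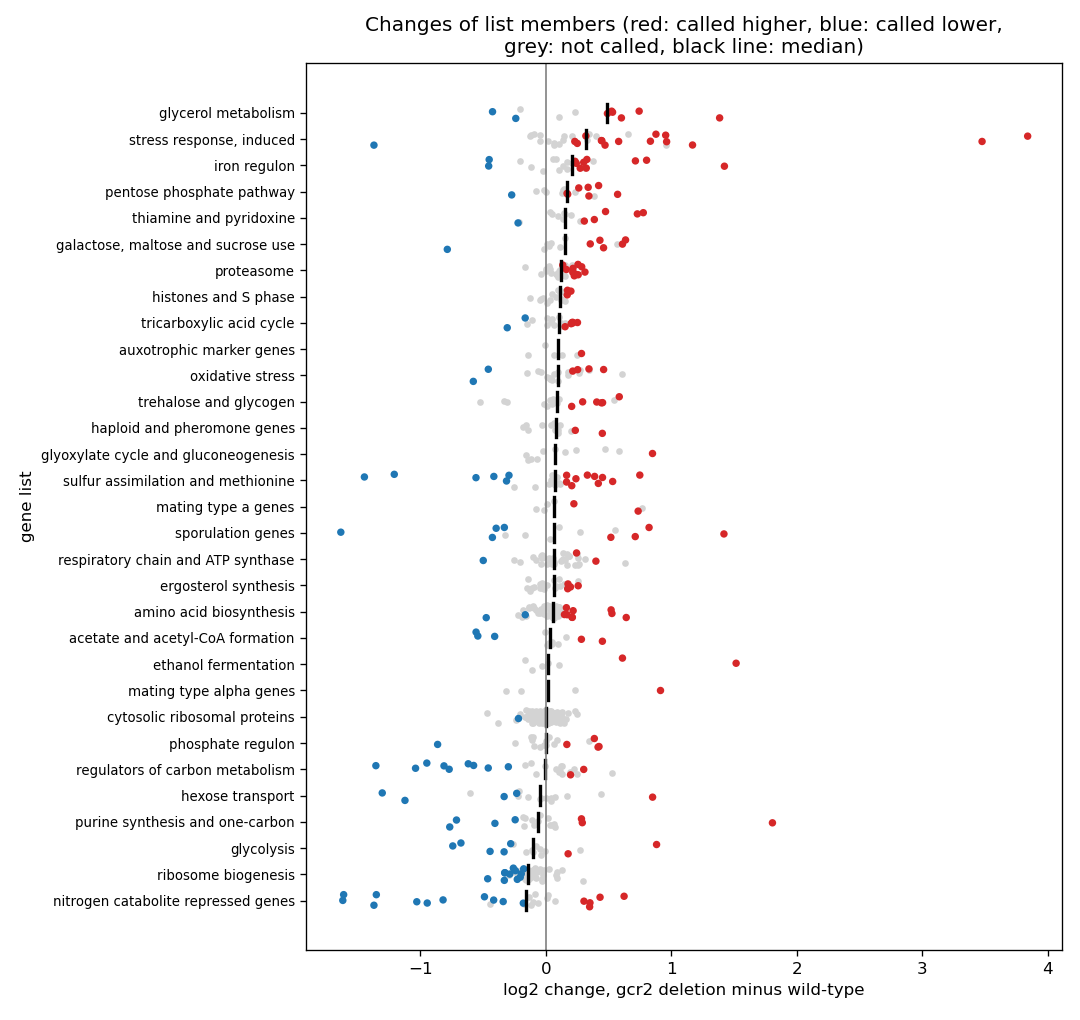
Log2 change, deletion minus wild-type (horizontal axis), of each member of the 31 gene lists (vertical axis), with called members in red (higher) or blue (lower), others in grey and the list median in black. Stress genes reach 3.84, nitrogen catabolite genes fall to -1.62, and cytosolic ribosomal protein genes lie around 0.

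Nitrogen catabolite repressed genes, which serve the use of poor nitrogen sources, fell in 11 of 26, rose in 5 and did not pass in 10. PUT1, proline oxidase, fell by 1.62 (SE 0.07, adjusted p = 0.00013), DAL80, a repressor of the same genes, fell by 1.61, and the transporter genes DAL4 and DAL5 fell by 1.37 and 1.35. The list's median was -0.16 (camera adjusted p = 0.00046; adjusted p = 0.31 with an estimated correlation). Sulfur genes went both ways, with 10 of 27 up, 6 down and 11 not called, a median of 0.07 and a mean of -0.01. The sulfate transporter gene SUL1 fell by 1.45 (adjusted p = 0.0016) and the methionine permease gene MUP1 by 1.21, and MET2 rose by 0.45. Of 61 amino acid biosynthesis genes 9 rose, 2 fell and 50 did not pass, with PRO1 up by 0.53. Of 19 purine and one-carbon genes 3 rose, 4 fell and 12 did not pass. IMD2, for the enzyme that commits to GTP synthesis, rose 3.49-fold (adjusted p = 4.71e-05) on a probe set that can bind related transcripts. GCV1 and GCV2 of the glycine cleavage system fell by 0.77 and 0.71.

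Iron regulon genes rose in 9 of 23, fell in 2 and did not pass in 12. ENB1, a siderophore transporter gene, rose by 0.80 (adjusted p = 0.00065) and HMX1, heme oxygenase, by 0.71, whereas FIT1 fell by 0.45. Thiamine and pyridoxine genes rose in 5 of 15, fell in 1 and did not pass in 9 (10 and 1 adjusted over the list alone), with THI2, their regulator, up by 0.73. Camera called both lists (adjusted p = 0.019 each), but with an estimated correlation both had an adjusted p = 0.72. Without wild-type replicate 2 the values were 0.0503 for iron and 0.063 for thiamine. Proteasome genes rose in 10 of 33 and did not pass in 23, by small amounts such as 0.29 for RPT3 and 0.26 for PUP1, with a list median of 0.12 (camera adjusted p = 0.0017; adjusted p = 0.72 with an estimated correlation). In the phosphate regulon 4 of 18 rose, 1 fell and 13 did not pass, with PHM6 down by 0.86. In ergosterol synthesis 4 of 23 rose, led by ERG9 at 0.26, and 19 did not pass. Among histones and S phase genes 3 of 19 rose and 16 did not pass, with CLN2 up by 0.20.

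Other genes among the 10 largest rises were YER053C-A (2.18), TDA6 (1.69), IRC15 (1.64), PRM9 (1.59), FMP48 (1.5) and YBL005W-A (1.48). The aquaporin gene AQY1 fell from 9.33 ± 0.16 to 7.33 ± 0.07 (adjusted p = 0.0002), and EEB1, for an enzyme that makes ethyl esters, fell by 1.89 (adjusted p = 0.00011). LEE1 fell by 1.73, SPS4 by 1.63, ATG39 by 1.59 and YLR154C-H by 1.54. The probe sets of YBL005W-A and YLR154C-H can bind related transcripts.

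**Figure D4:**
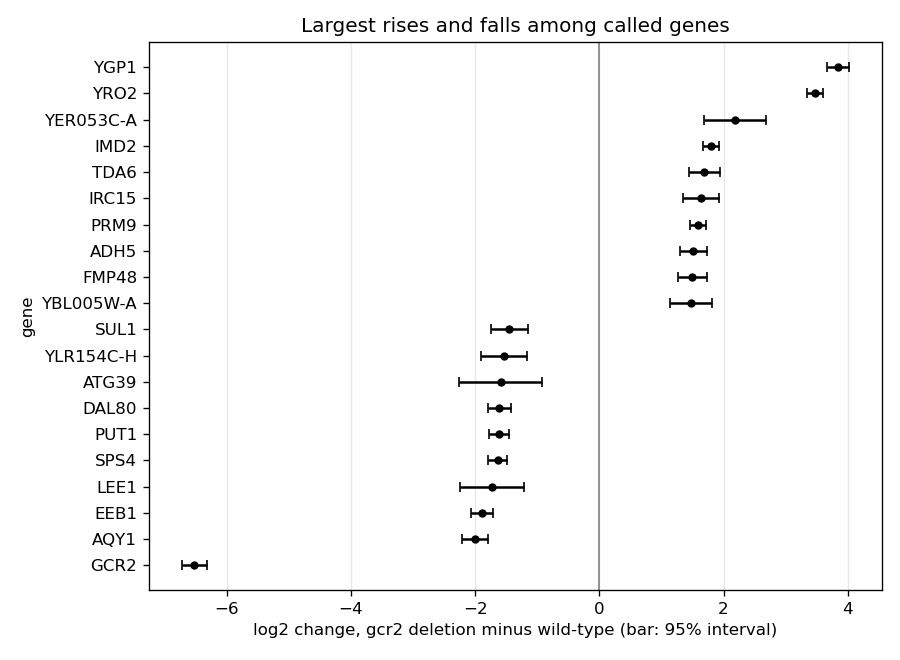
Log2 change, deletion minus wild-type (horizontal axis), with 95% intervals from limma for the 10 largest rises and 10 largest falls among called genes (vertical axis). YGP1 and YRO2 exceed 3, GCR2 lies at -6.52 with its deletion level under background, and YER053C-A, next among the rises, lies at 2.18.

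Marker genes of other cell types were checked in both groups. Of 7 genes of mating type a, ASG7 rose by 0.74 and BAR1 by 0.22, and 5 did not pass; STE2, the alpha-factor receptor gene, was at 14.16 ± 0.07 and 14.23 ± 0.01. Of 4 genes of mating type alpha, STE3 rose by 0.91, from 7.53 ± 0.06 to 8.44 ± 0.07, and 3 did not pass. BAR1 lost its call in 11 of 16 alternatives and ASG7 in 3. Of 14 haploid and pheromone genes 2 rose, FUS3 by 0.45 and FAR1 by 0.23, and 12 did not pass. Of 14 sporulation genes 4 rose, 4 fell and 6 did not pass; HOP1 rose by 1.42, from a level above background on 1 of 3 wild-type arrays, and IME1 fell by 0.33. The median of that list was 0.07 and camera's direction was down. Among 6 measured auxotrophic markers LEU2 rose by 0.28 and 5 did not pass, with URA3 at 12.78 ± 0.04 and 12.84 ± 0.05 and LYS2 at 13.38 ± 0.01 and 13.37 ± 0.01. Several calls named above were lost in some of 16 alternatives: CLN2 in 9, RPS9A in 8, RKI1, TPS2 and CIT1 in 6, FAR1 in 5, FUM1 and ERG9 in 4, ZWF1 and PUP1 in 3, and ATG39, GPX2, FIT1, RPT3 and LEU2 in 1.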

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

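The tests of ribosomal protein genes and of control probe sets were chosen after those values had been seen; the splits, the brightness tests and the test of single arrays were fixed before theirs.

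Data that the gene tests did not use held signals above the wild-type level on all 3 deletion arrays. A reporter control probe set was at 4.62 ± 0.15 in wild-type, under background on all 3 arrays, and at 14.58 ± 0.01 in the deletion, at least 303-fold higher. Its sequence was not analysed here. Probe sets that the annotation does not list were higher by 2.26, 1.68, 1.36, 1.02 and 1.01. The values 1.68 and 1.36 rested mostly on deletion replicate 1, where these probe sets read 10.59 and 10.18 against 8.06 or less on the other arrays.

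The 1224 called genes and the 51 changed at least 2-fold came from the real grouping. Each of the other 9 of the 10 splits of the 6 arrays gave 0 of either with limma (9 to 349 genes at an unadjusted p under 0.05, against 2093), so 1 split of 10 gave as large a result in both cases. The number of called lists was 8 in the real grouping, but 2 of the 10 splits gave as many or more, and the highest other split gave 10. With 3 arrays against 3 the splits are too few for a share under 0.05.

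Some glycolytic genes fell while others of similar brightness did not pass. As a test for a shift of all bright probe sets, 74 genes outside the list, as bright as the fallen members, were compared. Their median change was 0.011. RMA equalises the intensity distributions of the arrays, the bright end included, so a small median was largely set in advance. It cannot decide whether the normalization shifted the glycolytic genes. All 5 fallen members lay under the 5th percentile of those genes, -0.08. They had been picked because they fell, so their position does not bear on a shift either. A signal ceiling stays open. Of 149 genes outside the list, as bright as the 6 uncalled members at 14.16 or above, 6.04% were called. The exact binomial 95% interval was 2.8 to 11.2, taking genes as independent, against 22.0% at log2 10 to 13. The 90th percentile of the absolute log2 change was 0.14 in those 149 genes, against 0.35 at log2 10 to 13. Neither measure can tell a ceiling from bright genes that did not change. The 5 fallen members were themselves at 14.41 or above, so some falls could be read at that brightness. Having been picked because they fell, they do not show that most falls can be read there. A ceiling may still hide falls in TDH3, PGK1 or FBA1. Unequal dependence of these genes on Gcr2 stays open too and was not tested.

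Of 33 stress genes 14 rose and 1 fell, and of 53 ribosome biogenesis genes 11 fell. Camera called both lists with its preset correlation, and neither with an estimated correlation (adjusted p = 0.72 each). Fry called the stress list (adjusted p = 0.0045) but not the ribosome biogenesis list (adjusted p = 0.085). With the preset correlation a single array did not carry the calls, since the highest adjusted p of both lists without any 1 array was 0.0011. Slower growth of the deletion strain could lower ribosomal protein genes too. Their mean change was -0.011, with a 95% interval over arrays from -0.16 to 0.14, which leaves a fall of 0.1 possible, so slower growth cannot be told apart from other effects of the deletion.

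Ribosomal RNA and poly-A controls were lower on the deletion arrays. RNA degradation in 1 group is argued against, since the 3' minus 5' difference of 6 yeast control genes differed by 0.0050 between groups (95% interval -0.03 to 0.04). Weaker hybridization was not decided by its test. The hybridization controls differed by -0.15, with an interval from -0.52 to 0.21 that includes the bound of -0.43 set for it. Deletion replicates 2 and 3 read as wild-type there, at 11.48 and 11.49. Their ribosomal RNA controls were at 12.75 and 12.46, against 13.73 or more in wild-type. Deletion replicate 1 was at 11.09. RMA had equalised the arrays before these values were read, so they cannot show whether a whole array hybridized more weakly. Weaker hybridization therefore stays open for the deletion arrays. A larger share of messenger RNA in the deletion samples could lower both kinds of control. Their changes differed by -0.47 (95% interval -1.25 to 0.30). For the poly-A controls, a different amount of spike-in added to each group cannot be told apart from a larger share of messenger RNA. A spike-in amount would not lower the ribosomal RNA controls, whose change was -1.33 (95% interval -1.84 to -0.81). These values argue against it as the cause of both falls.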

How the results depend on the processing

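Centring on poly-A controls and leaving out wild-type replicate 3 with deletion replicate 1 were chosen after seeing the data. GCR2 stayed called in every alternative run for it, between -6.57 and -6.43 without single arrays. Leaving out 1 array gave 406 to 1225 called genes (239 to 751 higher, 167 to 474 lower), 47 to 54 changed at least 2-fold, 6 to 9 called lists, and a glycolysis median between -0.12 and -0.07. Array weights gave 1807 called genes, 1204 of them shared with the main fit. The weights were uneven, from 0.32 for wild-type replicate 3 to 4.06 for deletion replicate 3. The replicate numbers did not consistently pair the samples, since deviations of same-numbered arrays correlated at 0.53, -0.17 and -0.44. Under other numbers, wild-type replicate 2 with deletion replicate 3 gave 0.49, and wild-type replicate 3 with deletion replicate 2 gave 0.58. The remaining pairs gave 0.10 or lower. A pairing under other numbers therefore stays possible, and no fit allowed for it. With the replicate number as a block 733 genes were called, 433 higher and 300 lower. Without wild-type replicate 3 and deletion replicate 1 the counts were 328, 199 and 129. Each of the 10928 probe sets was also tested on its own, with those of the other species, unlisted ones and controls included. That called 467 probe sets (264 and 203), of which 377 were genes shared with the main fit, and 13 lists. Adjustment there was over more tests, and camera set the lists against those added probe sets too. An adjusted p under 0.01 left 347 (224 and 123), which follows from the threshold, the unmoderated statistic left 287 lower genes, and treat against 1.5-fold left 30 genes. Centring on poly-A controls gave 4891 calls (4882 and 9) and 1464 at least 2-fold, because it moves every gene by 0.86. Camera with an estimated correlation called 0 lists (2 at an unadjusted p under 0.05) and fry 16. For glycolysis the median was -0.10 and the adjusted p 0.72 with the estimated correlation, against 0.00069 to 0.031 under the others. Elsewhere the cause was not tested. Poly-A centring was not run for single named genes; of 892 genes called both with it and without, 778 kept their direction. In the 16 alternatives run for single genes none of 160 named genes besides GCR2 changed sign after being called; 248 comparisons of a gene with an alternative lost a call, 32 gained one and 2278 did neither. For lists other than glycolysis 11 lost a call, 19 gained one and 492 did neither. The 127 genes at or under background are limited by signal.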

Other observations

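Genes outside the naming rule, chosen after their values were seen, included further changes of at least 2-fold. Cell wall genes TIP1 and SPI1 rose by 1.31 and 1.17. URH1, a nucleoside hydrolase gene, rose by 1.23, and FUI1, a uridine permease gene, fell by 1.05. GPM2, a relative of GPM1 without known mutase activity, rose by 1.04 while GPM1 fell by 0.68. FIT2, a cell wall protein gene of the iron regulon, rose by 1.42, and PUT4, a proline permease gene, fell by 1.03 beside PUT1.

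A probe set not listed in the annotation went from 7.51 ± 0.81 to 4.32 ± 0.41, under background on all 3 deletion arrays and at least 2.27-fold lower. Another unlisted probe set read 12.26 on deletion replicate 3 and 5.18 or less on the other 5 arrays. Median changes of the 16 chromosomes lay between -0.003 and 0.048.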
